A study of Mus musculus with 4 samples.

How the data were processed

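Gene expression was measured on 4 microarrays hybridised with biotin-labelled total RNA of CCR6+ group 3 innate lymphoid cells (ILC3) from the mesenteric lymph node of naive C57BL/6 mice. ILC3 are lymphocytes that lack rearranged antigen receptors. Per the labels' protocols, nodes were broken up through a strainer and cells were sorted into an RNA extraction reagent as CD127+ CD90.2+ CCR6+ ST2- cells, and the labels give no further marker of the gate. The 4 samples form 1 group and are numbered 1 to 4. No second group was analysed, so no difference between conditions or cell types was tested. The labels do not say whether the samples came from separate animals, pools or sorts, so the p-values that use the spread between arrays measure only the spread between these samples, which may be partly technical.

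The deposited values are log2 levels per probe set, made with RMA (robust multi-array average) per the submitters' processing notes. RMA corrects background, normalizes arrays to each other and summarises the probes of each set. Its version and the software are not given in the sources used here. Of the genes above background, 10.9% had the same value to all printed digits on at least 2 arrays, which the median polish step of RMA can produce, and the SD of such genes can be too small. Scanner files were not used here, so the background correction could not be varied. The table held 35556 probe sets, and all of its columns belonged to the 4 samples.

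Probe sets were named through GEO's platform annotation. A single gene symbol was given for 21789 probe sets, several symbols for 1621, which were left unnamed, and 12146 were not listed. Of the singly named probe sets, 21698 had an Entrez identifier in the RefSeq gene table of assembly GRCm38.p6, which was used to update symbols only. No genome build is given in the sources used here, so no coordinates are reported. The named probe sets stood for 19938 genes. For the 999 genes with more than 1 probe set, the probe set with the highest mean was used.

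Probe sets differ in how well they bind, so each gene was set against background and not against other genes as an amount of RNA. The background was 1241 genes of the olfactory, vomeronasal, trace amine and bitter taste receptor families. The detection p of a gene was 1 plus the number of background genes with a mean at or above its own, divided by 1 plus the number of background genes. It was one-sided, could not fall below 0.000805 and was adjusted over all named genes by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 are called above background. Of the background genes themselves, 27 were called. A list of 16 genes of other organs served as a negative control. Because 6 of them were called, each count is accompanied by the number of genes above all 16 on every array, a reading chosen after the data were seen.

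The tests, 23 gene lists fixed by symbol, 8 gene families fixed by a pattern in the symbol, and the rule for named genes were set before the data were examined. Of the 307 list members fixed by symbol, 28 are not analysed here, 9 of them because their probe sets carry several gene names. The median level of each list was placed among 10000 random lists of the same size drawn from all named genes, as a description. Joint movement was the SD over the 4 arrays of the mean of a list's members above background, for the 27 lists with at least 3 such members. It was compared with 10000 random lists of the same size, drawn from genes above background in the same of 20 classes of mean level. The permutation p was one-sided and adjusted over the 27 lists. Genes are not independent of each other, so this test describes these 4 arrays. Random lists were matched on level but not on SD, so a few very variable members can make a list pass without the others moving alike.

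The rule for named genes took all sort gate genes. In each of 5 lists on ILC3 and antigen presentation it took up to 12 members above background and up to 4 that were not. In every other list it took up to 4 members above background and up to 2 that were not. It also took the 10 genes with the highest mean and the 10 genes above background with the largest SD. Any other gene named was chosen after its values were seen.

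The calculations were tested on simulated data. With 19938 genes in the test, 4% of genes simulated at background level were called, 11% of those raised by 1 log2 unit, 42% of those raised by 2 and 100% of those raised by 4, so genes at low levels can be missed. The simulated levels were drawn from the background genes themselves, which largely sets the 4%. It is no rate of false calls for other silent genes, as 6 of the 16 genes of other organs were called. With 9369 genes in the test, lists of 11 genes moved by 0.25 log2 units, up on 2 arrays and down on the other 2, passed an unadjusted p of 0.05 in 100% of cases, and unmoved lists in 3%. The simulated genes varied independently of each other, so the 3% does not give the rate for real lists of genes that vary together. The number of arrays limits the precision of every level. Alternatives covered the detection rule, the background genes, the choice among probe sets, the normalization, the genes included, the matching of random lists and the arrays included. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for an alternative detection test.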

Results

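The data describe which genes sorted CCR6+ ILC3 of the mesenteric lymph node carried above background and how far 4 samples of these cells differed. The median log2 level of all probe sets was 6.03, 6.03, 5.99 and 6.01 on arrays 1 to 4. Of 19938 named genes, 9203 (46.2%) were above background, the lowest at a mean of 6.37, and 11443 had an unadjusted detection p under 0.05. All 11 housekeeping genes measured were above background, also when adjusted over the list alone, and above all genes of other organs, with Actb at 13.03 ± 0.06 (SD, n = 4, as for all levels that follow), B2m at 12.84 ± 0.02, Eef1a1 at 12.73 ± 0.03 and Rplp0 at 12.31 ± 0.05. Of the 16 genes of other organs, 6 were called, or 3 when adjusted over the list alone. Ckm, the muscle creatine kinase, was at 7.33 ± 0.14, Apoa1, a liver apolipoprotein, at 7.24 ± 0.11, Tnnt3 of muscle at 7.08 ± 0.11 and Syp of synapses at 6.56 ± 0.15. Ttr at 6.21 ± 0.15 and Prm1 at 6.00 ± 0.10 were not called, although Ttr was without array 2. The highest value of these genes on any array was 7.42, so calls up to that level carry little weight, and 4987 genes lay above all 16 on every array.

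The genes of the sort gate were first examined. Il7r, which encodes CD127, was at 12.56 ± 0.06, Thy1, which encodes CD90, at 11.36 ± 0.15, and Ccr6, the receptor for the chemokine CCL20, at 10.49 ± 0.09. These 3 genes were above background, also when adjusted over the list alone, and above all genes of other organs on every array, with an adjusted detection p of 0.0108 each. The gene of the marker excluded by the gate is not analysed here.

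Transcription factors known from ILC3 were above background in 13 of 13 cases, also when adjusted over the list alone, and 11 were above all genes of other organs. Id2, which represses E proteins and is needed by innate lymphoid cells, was at 11.54 ± 0.12. Runx3 was at 10.23 ± 0.20, Ets1 at 10.02 ± 0.09, Rora, a nuclear receptor, at 9.88 ± 0.12, Gata3 at 9.72 ± 0.12, Tox at 9.60 ± 0.18 and Batf at 9.501 ± 0.347. Runx1 was at 8.66 ± 0.15, Ahr, the aryl hydrocarbon receptor, at 8.19 ± 0.20, Tox2 at 7.92 ± 0.35 and Nfil3 at 7.75 ± 0.35. Ikzf3, at 7.30 ± 0.73, ranged from 6.31 on array 4 to 7.91 on array 1. The median of the list lay above that of all 10000 random lists.

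Receptors and homing molecules of ILC3 were above background in 14 of 15 cases, in 15 when adjusted over the list alone, and 14 were above all genes of other organs. The cytokine receptor genes Il2ra, Il18r1 and Il23r were at 11.46 ± 0.09, 11.41 ± 0.11 and 11.24 ± 0.06. Cd4, found on many lymphoid tissue inducer cells but also on T cells, was at 10.96 ± 0.13. Cxcr6 was at 10.78 ± 0.10, Gpr183, an oxysterol receptor, at 10.59 ± 0.22, Kit, the receptor for stem cell factor, at 10.57 ± 0.18 and Itga4 at 10.32 ± 0.18. Icos was at 9.91 ± 0.44, Nrp1 at 9.16 ± 0.15, Ccr7, which guides cells into lymph nodes, at 9.06 ± 0.26 and Tnfrsf25 at 8.96 ± 0.15. Ccr9, a gut homing receptor, was at 5.83 ± 0.42 and not called over all genes.

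Among effector cytokines, lymphotoxin and TNF genes were above background while Il17a and Il17f were not. In all, 6 of 15 were called, also when adjusted over the list alone, and 5 were above all genes of other organs. Ltb was at 11.33 ± 0.07 and Lta at 9.998 ± 0.315, both encoding lymphotoxin chains, Tnf at 9.69 ± 0.26, Tgfb1 at 8.71 ± 0.30 and Tnfsf11, which encodes RANKL, at 8.14 ± 0.21. Il13, at 6.69 ± 0.37, was called within the range of the genes of other organs. Il17f at 5.90 ± 0.04, Il17a at 5.87 ± 0.42, Ifng at 5.62 ± 0.06 and Csf2 at 6.26 ± 0.56 were not called, although Csf2 was without array 3, at 6.53. Il17f did lie above the 95th percentile of background on every array. That looser rule called 7 effector cytokines, but also 9 of the 16 genes of other organs. Il22 shares its probe sets with another gene and is not analysed here.

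Genes of antigen presentation on MHC class II were above background in 13 of 13 cases, also when adjusted over the list alone, and 10 were above all genes of other organs. Cd74, the invariant chain, was at 11.93 ± 0.12, and the class II chains H2-Ab1, H2-Aa and H2-Eb1 were at 11.71 ± 0.13, 11.71 ± 0.17 and 10.71 ± 0.20. Ctss, a protease that degrades the invariant chain, was at 10.67 ± 0.12, H2-Oa at 10.49 ± 0.18, H2-DMa at 9.06 ± 0.09, Ctsb at 8.27 ± 0.29, Ciita, the class II transactivator, at 7.99 ± 0.36 and Ctsl at 7.16 ± 0.26. Ifi30 at 8.69 ± 0.66 and H2-Ob at 8.04 ± 0.92 differed most between arrays among the named members. B cells also carry these genes, and B cell markers were above background on the same arrays, with list means of 8.90, 7.95, 9.08 and 7.83 on arrays 1 to 4. On arrays 2 and 4 alone, which had the lowest B cell markers and were singled out after the data were seen, 12 of the 13 were above background, but so were 10 B cell markers, so these arrays do not show the list without B cell signal.

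Of 10 costimulatory and coinhibitory ligands, 5 were above background, also when adjusted over the list alone, and 3 were above all genes of other organs. Tnfsf4, which encodes OX40 ligand, was at 9.38 ± 0.38, Icosl at 9.27 ± 0.14 and Cd274, which encodes PD-L1, at 8.22 ± 0.33. Pdcd1lg2 at 7.28 ± 0.11 and Cd40 at 7.11 ± 0.39 were called within the range of the genes of other organs. The classical costimulators Cd80 and Cd86, at 5.73 ± 0.37 and 5.60 ± 0.32, were not called, nor were Tnfsf18 at 6.15 ± 0.31 and Cd70 at 6.02 ± 0.13.

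**Figure D1:**
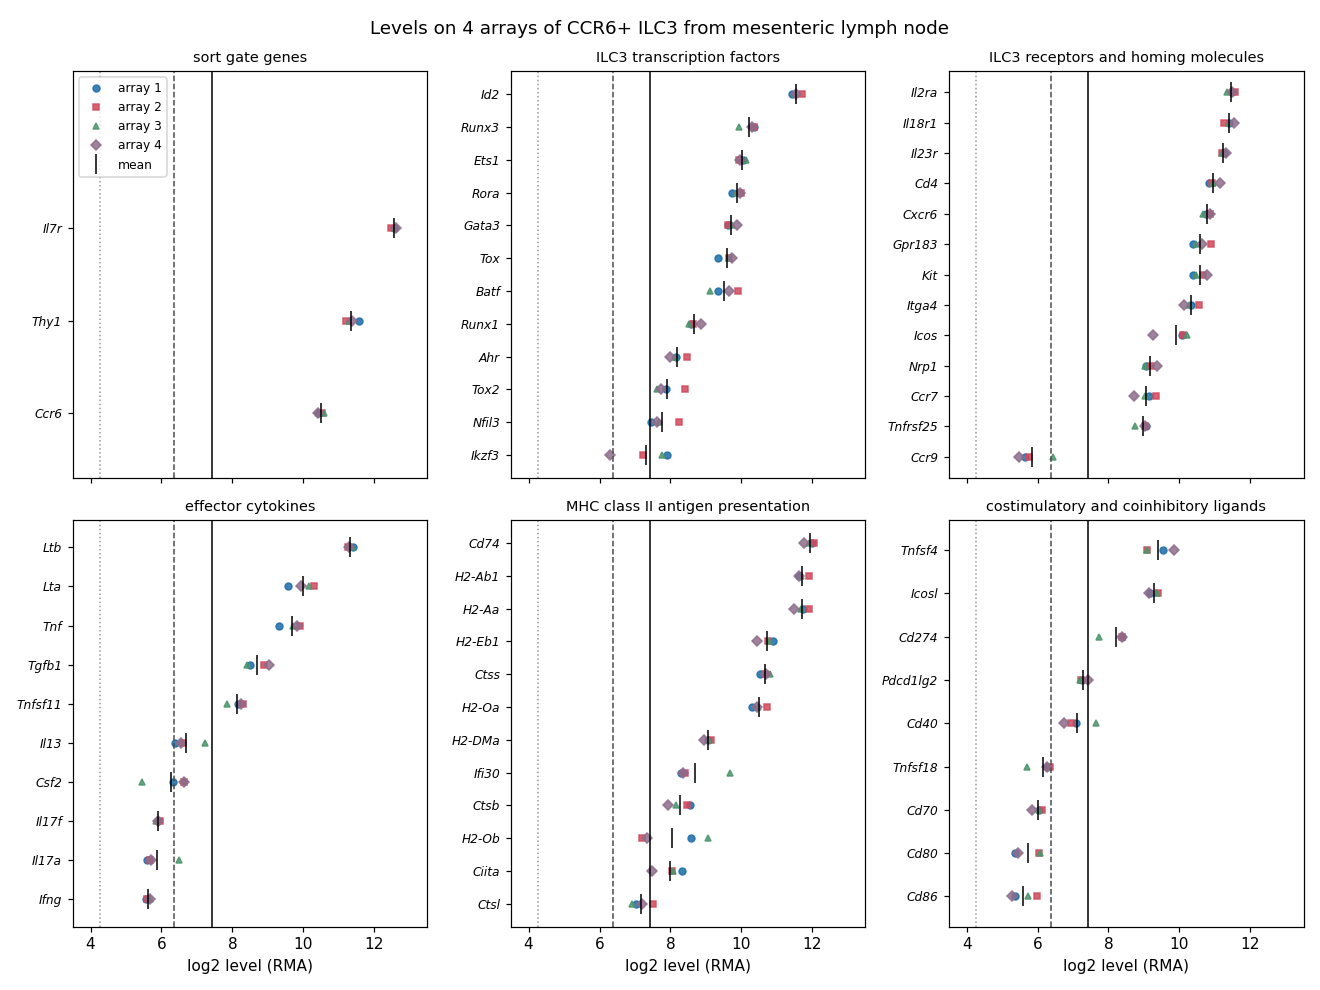
Log2 levels of the named genes of 6 lists, with 1 symbol per array and a vertical tick at the mean of the 4 arrays. The dotted line is the mean of the arrays' background medians (4.25), the dashed line the lowest mean called above background (6.37) and the solid line the highest value of any gene of other organs (7.42), and Ltb, Lta and Tnf lie right of the solid line while Il17a, Il17f, Cd80 and Cd86 have means left of the dashed line.

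Markers of other cells that a sort of lymph node could hold were examined next. B cell markers were above background in 11 of 12 cases, in 12 over the list alone, and 10 were above all genes of other organs. Cd79b and Cd79a, signalling chains of the B cell receptor, were at 9.84 ± 0.55 and 8.84 ± 0.78, Pou2af1 at 9.19 ± 0.35 and Bank1 at 8.76 ± 0.91, and Fcrla at 5.96 ± 0.38 was not called. T cell markers were above background in 11 of 13 cases, 12 over the list alone, with 4 above all genes of other organs. Cd3e, Cd3g and Cd3d, chains of the T cell receptor complex, were at 8.91 ± 0.22, 8.77 ± 0.50 and 8.32 ± 0.44, and Cd8b1 was at 7.66 ± 0.55. Themis at 6.15 ± 0.30 and Trat1 at 4.27 ± 0.30 were not called. Whether T cells contributed to the levels of Cd4 and of other genes given above for ILC3 was not tested.

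Markers of natural killer (NK) cells and ILC1 were above background in 9 of 15 cases, 9 over the list alone, with 4 above all genes of other organs. Ccl5, a chemokine gene, was at 9.81 ± 0.83, Klrk1 at 8.28 ± 0.61, Xcl1 at 8.06 ± 0.58 and Klrb1c, which encodes NK1.1, at 8.02 ± 0.05. Itga2 at 5.63 ± 0.26 and Gzma at 6.11 ± 1.23 were not called, although Gzma was without array 1, at 6.41. Of 9 ILC2 markers 5 were called, 6 over the list alone, with Gata3 above all genes of other organs. Arg1, an arginase, was at 7.67 ± 0.79 and Il17rb at 6.69 ± 0.55, and Ptgdr2 at 6.32 ± 0.04 and Hpgds at 5.17 ± 0.25 were not called. Ptgdr2 was called without array 1 or array 2, at 6.32 each, and 3 ILC2 markers were called on arrays 2 and 4 alone.

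Myeloid and structural markers were mostly not above background. Dendritic cell markers were called in 5 of 12 cases, 5 over the list alone and 1 above all genes of other organs, with Batf3 at 8.94 ± 0.19, Fscn1 at 7.33 ± 0.71, Ccl17 at 7.12 ± 0.49 and Ccl22 at 6.54 ± 0.65. Flt3 at 6.26 ± 0.16 and Siglech at 5.90 ± 0.08 were not called, and Ccl22 was not without array 3, at 6.31. Of 12 monocyte and macrophage markers 2 were called, 1 over the list alone and 1 above all genes of other organs. Lyz2, a lysozyme gene, was at 8.22 ± 0.73 and Cd68 at 6.94 ± 0.46. Adgre1 at 6.32 ± 0.46 and C1qb at 6.27 ± 0.60 were not called, although both were without array 2 or without array 4, at 6.38 and 6.42 for Adgre1 and 6.33 and 6.50 for C1qb. Adgre1 was also called without array 1, at 6.40. Of 11 neutrophil markers 0 were called, also over the list alone, by the detection test or by limma, and 0 were above all genes of other organs, with Elane at 5.87 ± 0.08 and Camp at 5.74 ± 0.10. Of 5 erythroid and platelet markers 0 were called, also over the list alone, and 0 were above all genes of other organs, with Gp9 at 6.11 ± 0.13 and Itga2b at 6.08 ± 0.10, while limma's test called 2 and the 95th percentile of background 3. Stroma and endothelium markers were called in 5 of 15 cases, 3 over the list alone and 1 above all genes of other organs, with Pecam1 at 8.44 ± 0.18, Ccl19 at 6.94 ± 0.20, Col1a1 at 6.93 ± 0.09 and Col1a2 at 6.56 ± 0.06. Col3a1 at 6.23 ± 0.06 and Pdgfra at 5.74 ± 0.04 were not called. Of 10 epithelial markers 1 was called, 0 over the list alone and 0 above all genes of other organs, Krt8 at 6.88 ± 0.14, and Muc2 at 5.38 ± 0.04 and Krt18 at 5.35 ± 0.24 were not.

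Lists on cell state showed clock and immediate-early genes above background and few cell cycle genes. Of 13 circadian clock genes 12 were called, 12 over the list alone and 8 above all genes of other organs. Nr1d1, which encodes the repressor REV-ERBα, was at 11.03 ± 0.16, Bhlhe40 at 9.34 ± 0.15, Nr1d2 at 8.89 ± 0.08 and Dbp at 8.34 ± 0.23, and Bhlhe41 at 4.20 ± 0.24 was not called. Of 17 immediate-early and heat shock genes 14 were called, 14 over the list alone and 9 above all genes of other organs. Jun was at 9.66 ± 0.08, Zfp36 at 9.31 ± 0.20, Dusp1 at 8.62 ± 0.18 and Junb at 8.25 ± 0.16, while Atf3 at 5.66 ± 0.28 and Nr4a2 at 5.61 ± 0.02 were not called. Interferon response genes were called in 9 of 13 cases, 9 over the list alone and 4 above all genes of other organs, with Rtp4 at 9.87 ± 0.31, Bst2 at 9.78 ± 0.21, Ifit3 at 8.77 ± 0.09 and Usp18 at 7.89 ± 0.51. Rsad2 at 5.56 ± 0.26 and Ifit2 at 5.38 ± 0.38 were not called. Of 15 cell cycle genes 5 were called, 1 over the list alone and 1 above all genes of other organs. Pcna, which also serves DNA repair, was at 10.56 ± 0.03, Mcm2 at 7.03 ± 0.20, Tyms at 6.85 ± 0.13 and Mcm5 at 6.68 ± 0.16, and Mki67 at 6.09 ± 0.20 and Ccnb2 at 6.00 ± 0.21 were not called. Neuropeptide and neurotransmitter receptors were called in 6 of 11 cases, 6 over the list alone and 3 above all genes of other organs. Ramp1, a subunit of the receptor for calcitonin gene-related peptide, was at 9.12 ± 0.15, Vipr2, a receptor for vasoactive intestinal peptide, at 8.98 ± 0.27, Calcrl at 7.66 ± 0.14 and Ret at 7.50 ± 0.25. Gfra3 at 6.05 ± 0.07 and Gfra1 at 6.00 ± 0.11 were not called.

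Gene families of signalling and adhesion gave a wider view. Interleukin receptors were called in 22 of 35 cases, 24 over the list alone and 11 above all genes of other organs, led by the Il7r, Il2ra, Il18r1 and Il23r values above. Il10ra at 6.33 ± 0.30 and Il17rd at 6.19 ± 0.01 were not called, although Il10ra was without array 2, at 6.45. Of 32 interleukins 5 were called, 0 over the list alone and 1 above all genes of other organs, including Il16 at 7.59 ± 0.06, Il27 at 7.46 ± 0.09 and Il15 at 6.90 ± 0.34, and Il17c at 6.04 ± 0.10 was not. Il17b, chosen after its values were seen, was called at 6.69 ± 0.08, within the range of the genes of other organs. Chemokines were called in 10 of 34 cases, 5 over the list alone and 3 above all genes of other organs, with Cxcl10, which interferon induces, at 8.59 ± 0.64 and Cx3cl1 at 8.20 ± 0.18. Ccl25 at 6.15 ± 0.16 and Ccl7 at 6.05 ± 0.08 were not called. Chemokine receptors were called in 10 of 21 cases, 10 over the list alone and 7 above all genes of other organs, among them Cxcr4, the receptor for CXCL12, at 11.33 ± 0.09, and Ackr3 at 6.06 ± 0.24 and Cxcr1 at 5.92 ± 0.14 were not. TNF superfamily ligands were called in 7 of 15 cases, 8 over the list alone and 7 above all genes of other organs, and in 11 by limma's test. Tnfsf10 at 6.27 ± 0.46 was not called, although it was without array 1 or array 2, at 6.46 and 6.32. TNF receptors were called in 17 of 27 cases, 18 over the list alone and 8 above all genes of other organs. Tnfrsf13c, the BAFF receptor of B cells, was at 8.78 ± 0.67, Tnfrsf26 at 8.13 ± 0.35 and Tnfrsf21 at 8.06 ± 0.30, and Tnfrsf1a at 6.13 ± 0.05 and Tnfrsf12a at 6.03 ± 0.06 were not called. Of 10 Toll-like receptors 4 were called, 4 over the list alone and 0 above all genes of other organs, with Tlr1 at 7.22 ± 1.29, Tlr4 at 6.78 ± 0.51, Tlr2 at 6.74 ± 0.25 and Tlr9 at 6.70 ± 0.32, and 2 on arrays 2 and 4 alone. Tlr6 at 5.73 ± 0.19 and Tlr12 at 5.63 ± 0.09 were not called. The pattern for integrins took 28 genes, 1 of them the binding protein Itgb3bp, and 9 were called, 9 over the list alone and 7 above all genes of other organs, while the 95th percentile of background and limma's test called 15 each. Itgb2 was at 9.54 ± 0.21, Itgal at 9.38 ± 0.13 and Itgb7, part of the gut homing integrin, at 8.91 ± 0.10. Itga3 and Itga10, at 6.30 ± 0.07 and 6.30 ± 0.01, were not called, although both were without array 2, at 6.31 and 6.30.

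The 10 genes with the highest means are named by rule, and their order is not a ranking of RNA amounts. Rps29 was at 13.42 ± 0.02, Rps28 at 13.17 ± 0.01, Rpl41 at 13.03 ± 0.01, Rplp1 at 12.96 ± 0.03 and Tmsb10, an actin-binding thymosin, at 13.19 ± 0.03, beside Actb and B2m. Baiap2l1 was at 13.39 ± 0.04, the small nuclear RNA Rn7sk at 13.29 ± 0.06 and Ly6e at 13.10 ± 0.05. Genes with the largest SD above background included immunoglobulin genes. Igha, the constant region of IgA, was at 7.27, 6.39, 10.66 and 6.33 on arrays 1 to 4, an immunoglobulin kappa variable gene at 7.26, 5.85, 10.29 and 5.98, and Rasgrp3 at 7.80, 5.89, 8.60 and 5.89. Adck1 was at 7.79, 8.65, 9.65 and 3.74. The SD was 1.70 for Mir202, 1.55 for I730030J21Rik, 1.51 for Mir181b-2, 1.42 for 1700056E22Rik, 1.32 for Snord53 and 1.30 for Snord87. The kappa variable gene was not called without array 3, and Snord87 was not without array 1 or array 3, at 6.09 and 6.18.

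The arrays were close to each other over most genes. The median SD of genes above background was 0.168 log2 units, a fold of 1.12, with a 5th percentile of 0.0393 and a 95th of 0.476. Pearson's r across genes above background lay between 0.948 and 0.962 in the 6 pairs of arrays, and between 0.964 and 0.971 across all probe sets. Genes are not independent replicates, so these r describe the arrays only.

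The means of some lists differed between arrays more than those of random lists did. B cell markers had an SD of the list mean of 0.641, against a median of 0.0673 for random lists, with an adjusted permutation p of 0.00135 over 27 lists. The unadjusted p, 0.0001, was the smallest that the random lists can give. Cd79a was at 9.59, 8.33, 9.43 and 8.03 on arrays 1 to 4 and Bank1 at 9.37, 8.04, 9.71 and 7.93, and 9 of the 11 members were higher on both arrays 1 and 3 than on both others. The MHC class II list had means of 9.49, 9.46, 9.67 and 9.22, with an SD of 0.182 and an adjusted permutation p of 0.009, but 0.123 without array 4. Housekeeping genes had an SD of 0.0318 and an adjusted permutation p of 0.874.

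The mean of the chemokine list had an SD of 0.296 (adjusted permutation p = 0.00135), but its members did not all move alike. The list shares Ccl5 and Xcl1 with the NK cell and ILC1 markers and Ccl17 and Ccl22 with the dendritic cell markers. The results of these lists are therefore not separate. Ccl5 was at 8.96, 10.31, 10.69 and 9.27 on arrays 1 to 4, Cxcl10 at 7.77, 9.07, 8.42 and 9.11, and Cxcl9, chosen after its values were seen, at 5.53, 7.64, 5.84 and 6.96. The adjusted permutation p of the chemokines was 0.0527 without array 1. Toll-like receptors had an SD of 0.399 (adjusted permutation p = 0.0135), with Tlr1 at 7.53, 6.48, 8.89 and 5.97, and lost the call without array 3 (0.169) or array 4 (0.0750). Tlr1 itself had an SD of 1.29, against 0.51 for Tlr4, 0.32 for Tlr9 and 0.25 for Tlr2. Dendritic cell markers had an SD of 0.355 (adjusted permutation p = 0.0139), with Fscn1, an actin-bundling protein, at 6.66, 7.69, 8.16 and 6.82, and an adjusted p of 0.168 without array 3. Immediate-early and heat shock genes had an SD of 0.186 (adjusted permutation p = 0.0139), with list means of 8.14, 7.89, 7.72 and 7.78, and an adjusted p of 0.446 without array 1. NK cell and ILC1 markers had an SD of 0.198 (adjusted permutation p = 0.0471), with list means of 7.78, 7.75, 7.80 and 7.38, and the adjusted p was 0.8997 without array 4 and 0.0559 with arrays centred on their medians. The other 20 lists did not pass, among them ILC3 transcription factors with an SD of 0.127 (adjusted permutation p = 0.0807) and ILC3 receptors with 0.0653 (adjusted permutation p = 0.402).

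**Figure D2:**
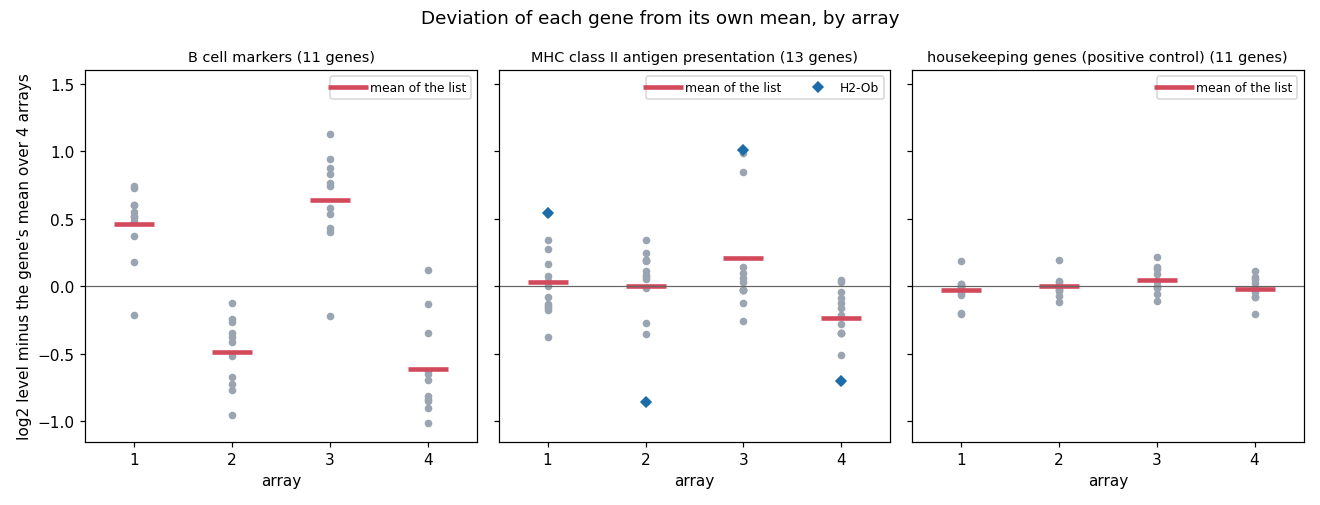
Deviation of each gene from its own mean over the 4 arrays, in log2 units, by array, for the members above background of the B cell, MHC class II and housekeeping lists, with 1 point per gene, a red bar at the list mean and H2-Ob as a diamond. The bars of the B cell list lie at 0.46, -0.49, 0.64 and -0.61 on arrays 1 to 4, while the list mean of the housekeeping genes has an SD of 0.0318.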

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

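The test for a single array apart from the other 3, and the results it was applied to, were not chosen after the results were seen. Of 217 results tested (named genes and list means), 17 had 1 array far from the others, where the test's rate of 1 in 20 would give 10.8. That rate is for normally distributed values without ties. Equal values on several arrays, which RMA can produce, make a flag more likely, as for Pecam1 below, so 10.8 may be too low. Array 3 stood apart in 10 of the 17. On array 3, Ifi30, a thiol reductase of antigen processing, was at 9.67 against 8.31 to 8.42 on the others, Cd3g at 9.51 against 8.47 to 8.59, Adgre1, a macrophage marker, at 7.003 against 6.03 to 6.15, and Il17a at 6.50 against 5.60 to 5.70. Lower on array 3 were Runx3 at 9.92 against 10.29 to 10.35, Tnfrsf25 at 8.74 against 9.02 to 9.05, Cd274 at 7.72 against 8.38 to 8.39, Tnfsf18 at 5.69 against 6.28 to 6.36, Ckm at 7.12 against 7.40 to 7.42 and Pecam1 at 8.17 against 8.53 on each of the others.

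On array 4, Icos, a costimulatory receptor, was at 9.25 against 10.07 to 10.20, Pdgfra at 5.67 against 5.76, Prm1 at 6.15 against 5.95 to 5.96, and the mean of the NK cell and ILC1 markers at 7.38 against 7.75 to 7.80. On array 1, Tmsb10 was at 13.15 against 13.21 and Itga3 at 6.40 against 6.26 to 6.28. On array 2, Ackr3 was at 6.41 against 5.90 to 5.97. No explanation was tested for these values.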

How the results depend on the processing

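The detection rule above all genes of other organs, and arrays 2 and 4 alone, were chosen after the results were seen. Of the results reported, B cell joint movement stayed past its threshold under every alternative run, with an SD from 0.588 to 0.689. With hair, epididymis and sperm genes as background, 0 genes were called, and 0 in each of the lists on the sort gate, ILC3, cytokines, MHC class II, costimulation and B cells. That set has 97 genes, so no p could fall below 0.0102. The smallest adjusted p was 0.143. The size of the set alone does not force this, because the adjusted p also depends on how many genes lie above these 97. The calls therefore depend on which genes serve as background. Against this set 4310 genes had an unadjusted p under 0.05, while limma's test against the sensory receptor genes called 10761 genes above background. Above all 16 genes of other organs on every array lay 4987 genes and 3 costimulatory ligands, by the construction of a stricter rule. With the 99th percentile of background, 2 ILC2 markers, 2 cell cycle genes, 2 interleukins, 1 dendritic cell, 1 stroma and 1 monocyte and macrophage marker, 4 chemokines, 3 genes of other organs, and 0 epithelial markers and Toll-like receptors were called. Without array 2 or array 4, 4 monocyte and macrophage markers were called. Over all named genes the median SD was 0.109 and the lowest r 0.983, and the cause was not tested. Leaving out 1 array gave 8835 to 9570 genes above background, a median SD of 0.153 to 0.157 and a lowest r of 0.949 to 0.956. It gave a joint SD of 0.112 to 0.223 for MHC class II, 0.0252 to 0.265 for NK cells and ILC1, 0.222 to 0.418 for dendritic cells, 0.231 to 0.488 for Toll-like receptors, 0.208 to 0.372 for chemokines and 0.0841 to 0.228 for immediate-early genes. Each of these 6 lists lost its call without at least 1 array, from fewer arrays or that array's values, and the cause was not tested. With arrays centred on their medians the NK cell and ILC1 SD was 0.197, no longer past the threshold, and the cause was not tested. Of the calls of 190 named genes, 190 were the same after quantile normalization, after centring and with the mean of a gene's probe sets, 178 on arrays 2 and 4 alone, 182 to 188 without 1 array, 161 with the 95th percentile of background and with limma, 160 with the 99th percentile, 53 with the hair, epididymis and sperm genes, and 147 with the stricter rule, where 43 were lost. Of the genes called, 8798 were also called on arrays 2 and 4 alone. No paired analysis was possible because there is only 1 group. Signal over background limits calls below 7.42.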

Other observations

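The gene families in this part, the tests of array shifts, of MHC class II genes and of Y-linked genes, the joint movement of a second B cell list and the search for other genes that followed the B cell markers were chosen after the results were seen. The bounds for the slope of that second list and for the test of different pools of mice were set before their own values were seen. Both tests nevertheless rest on the movement of the B cell markers already seen on these arrays. All 8 measured GIMAP genes, GTPases of lymphocyte survival, were above background and above all genes of other organs, with Gimap6 at 11.27 ± 0.14 (SD, n = 4) and Gimap3 at 10.64 ± 0.15. Of 22 killer cell lectin-like receptor genes 6 were above background and 4 above all genes of other organs, with Klrb1b at 12.05 ± 0.05 and Klrb1f at 11.23 ± 0.11. Of 25 genes of the Notch pathway 15 were above background and 10 above all genes of other organs, with the coactivator Maml2 at 8.95 ± 0.29, Rbpj, the transcription factor of the pathway, at 8.38 ± 0.47, the ligand Dll1 at 8.36 ± 0.25 and Notch2 at 8.23 ± 0.07.

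Nuclear receptors were above background in 16 of 45 cases and above all genes of other organs in 8. They included Nr2c2 at 9.52 ± 0.14 and the retinoic acid receptors Rara at 9.28 ± 0.12 and Rarg at 8.90 ± 0.13. Semaphorins, plexins and neuropilins, guidance molecules of axons and immune cells, were above background in 12 of 31 cases and above all genes of other organs in 7, with Sema4d at 8.89 ± 0.12 and Plxnc1 at 8.45 ± 0.12. Jchain, which joins chains of IgA and IgM, was at 7.96, 8.14, 9.96 and 6.96 on arrays 1 to 4, while Ighm was at 8.04, 8.92, 7.12 and 7.49. On the mean profile of the B cell markers over the arrays, the median slope was 0.206 for NK cell and ILC1, 0.215 for ILC2 and 0.105 for T cell markers, but Klrk1, Il17rb and Cd3d from these lists had 0.907, 0.847 and 0.674, and Lyz2, a monocyte and macrophage marker, 1.02.

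B cell markers moved together, at list means of 8.90, 7.95, 9.08 and 7.83 on arrays 1 to 4. No shift of whole arrays was seen, as housekeeping genes had an SD of 0.0318 and the B cell list kept 0.627 after quantile normalization. RMA had already normalized the arrays to each other, so this check had little room to find a shift. A candidate explanation is B cells carried along in differing amounts, although a gate on CD127 and CD90.2 would remove most of them. A second list of B cell genes followed the markers with a median slope of 0.256 (SE 0.0783, 16 genes above background). That lay between the bounds of 0.5 and 0.25 set for the test. Its members included Stap1 at 9.91 and Plcg2 at 9.27, with slopes of -0.03 and -0.18, while 3 members had a slope over 0.5. Genes that the sorted cells carry themselves would have a lower slope whatever the amount of B cells. Which members these are was not tested, so this slope cannot decide. The mean of the second list had an SD of 0.142 against 0.0558 for random lists (permutation p = 0.0092). The 5 immunoglobulin genes above background had a median slope of 1.502, although Ighm had -0.548. Of 11 measured, 0 lay above all genes of other organs. Igha and the kappa variable gene with the large SD were raised mainly on array 3. Another kappa variable gene was lowest on array 1, at 6.33, 7.18, 9.16 and 6.89 on arrays 1 to 4. Outside the B cell markers 21 genes above background had a slope over 1 and r over 0.9. Among them were Rasgrp3, Ly6d, Fcmr, H2-Ob, Syk, Btla, Blnk, Cd24a and a further immunoglobulin kappa variable gene. They also included Tlr1, Scd1, Cd55, Ly96, Taf1a, Ublcp1, Entpd5 and Apoe. The 23 other orders of the arrays gave 3 to 18, with a median of 5. Counts of 17 and 18 came only from orders that also set arrays 1 and 3 above 2 and 4, and the rest gave 3 to 9. Against the markers ran 12 genes above background, with a slope under -0.8 and r under -0.9, 5 of them under -1. Eif2s3y and Uty, not above background, also met both limits, with slopes of -3.06 and -1.50. Other orders gave 6 to 37. Counts of 31 and 37 came only from orders that reverse this pairing and so pick genes moving with the markers. The rest gave 6 to 18. B cells stay open, as do other cells, given the slopes of their markers above. Different pools of mice on arrays 1 and 3 than on arrays 2 and 4 also stay open as a cause of this movement. That pairing held 35.9% of the variance between arrays against 30.7% and 33.5% for the others, with the B cell markers, the Y-linked genes and Xist left out. Some Y-linked genes and Xist, given below, differed along this pairing. Those values bear on the mice, but not on whether the mice moved the B cell markers, and the labels give no groups to test as a cause.

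MHC class II genes were at high levels on every array. If B cells were the main source and the B cell markers tracked their amount, these genes would follow the markers. The markers have a median slope of 1.19 on their own mean profile, which is set largely by construction and is no benchmark for other B cell genes. The MHC class II list had a median slope of 0.0485 (SE 0.117), and Cd74, H2-Aa, H2-Ab1 and H2-Eb1 had slopes from -0.0745 to 0.215. These 4 genes therefore did not follow the markers. The second list of B cell genes also had a median slope of only 0.256 (SE 0.0783). Because the sorted cells may carry some of that list themselves, it gives no clear benchmark. B cells as the main source therefore stay undecided. Whether the markers track the amount of B cells is open as well. A share from B cells also stays open, as 4 of the 13 members were higher on both arrays 1 and 3 than on both others. A slope over 0.5 was found for 3 members. Of these, H2-Ob, with 1.41 and r of 0.985, may follow the B cell markers, while Lgmn with 0.695 had r of 0.780 and Ifi30 with 0.645 stood out on array 3 only. Other cells that carry MHC class II were not tested as a source.

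Of 9 measured genes of chromosome Y, 3 were over 1 log2 unit higher on arrays 2 and 4 than on arrays 1 and 3, Eif2s3y at 3.96, 7.24, 4.07 and 7.64 on arrays 1 to 4, Kdm5d at 5.70, 7.28, 5.85 and 7.06 and Uty at 4.04, 5.30, 3.88 and 5.89, while Sry, at 7.51, 7.21, 7.32 and 7.30, Usp9y, Zfy1, Zfy2, Uba1y and Srsy each had an SD under 0.3. Over the 4 arrays Eif2s3y and Uty were not called above background, while Kdm5d and Sry were. Kdm5d was seen first and is left out of the test, which was written after the other values were seen. Of the other 8 genes, 2 were higher on arrays 2 and 4 by over 1 log2 unit, against 5 of 19929 genes elsewhere. With a permutation p of 0.0002 for the 8 genes, this argues against noise of dim probes. The 4 genes looked at last, 3 of them not above background, did not move together (permutation p = 0.811). Genes that these cells may not carry at all could not rise, so this last result could not decide. Xist, from the inactive X chromosome of females, was above background, at 11.41, 11.04, 11.46 and 11.002, and its mean on arrays 2 and 4 was 0.42 log2 units lower, or 25.1%, so that a candidate explanation is that arrays 2 and 4 held RNA of male and female mice together and arrays 1 and 3 of females, which the labels neither state nor exclude, and why the other 6 genes did not rise was not tested. The arrays with this signal are also those with lower B cell markers.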
